A study of Mus musculus with 6 samples.

How the data were processed

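Total RNA of the V1 cortex was sequenced from 6 libraries, 2 for each of shControl, shCSB and shCSB/shNDN, made with a stranded total RNA kit per the labels' protocols. The series text gives 2 female mice per genotype, and the replicates were taken as separate animals. The FPKM values were made by the authors and deposited as 1 table with a column per library and 54532 entries. Per the submitters' processing notes, FastQC, HISAT2 2.0.4 and the build GRCm39 were used, and the counting program, its strand setting and the annotation release are not stated. The positions in the table equal those of GENCODE M21, which is on GRCm38, for 53585 of 54495 shared gene identifiers (98.3%), so coordinates are given as GRCm38. Because the strand setting is not stated, values of overlapping, antisense and near-identical genes are uncertain.

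Each deposited FPKM value times the gene length of the table was a whole multiple of 1 step per library, within 0.01, for 100% of values, so the reads behind each value were recovered. They came to 16781184 and 15731788 in shControl, 16192850 and 17365285 in the libraries labelled shCSB, and 16545933 and 16384738 in those labelled shCSB/shNDN. The library size behind the values differed from this total by a factor of 0.949 to 1.04, a scaling by the authors that no note describes. A count of 0 allows 3 reads, an FPKM of 0.169 to 0.201 for a gene of 1 kilobase, and covers counting error only. Gene symbols were those of the table. In it, 27 symbols had been turned into dates by a spreadsheet and were restored by gene identifier, and 100 symbols on several entries were summed, which left 54429 genes. Replicate pairs were compared by a chi-square test of their reads, and the statistic over its degrees of freedom was 10.8, 23.6 and 108, so no pair was within sampling noise.

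Genes with an FPKM of at least 0.5 in at least 2 of the 6 libraries were kept, 16254 in all. limma 3.58.1 in R 4.3.3 fitted group means to log2(FPKM + 1) over all 6 libraries, with a mean-variance trend, 3 residual and 3.42 prior degrees of freedom, and Benjamini-Hochberg adjustment over the genes kept, with a threshold of 0.05. The comparisons were shCSB against shControl, shCSB/shNDN against shCSB, shCSB/shNDN against shControl, and a moderated F test over the 3 groups. All p values are two-sided. Errors are standard errors of the fitted log2 change. The interval given for a targeted gene on the read scale comes from limma-voom.

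The groups, comparisons, 31 gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The lists cover imprinted genes of the Prader-Willi cluster and elsewhere, nucleotide excision repair, p53 targets, cell cycle, immediate early and stress genes, interferon response, antigen presentation, histones, respiratory chain, mitochondrially encoded, ribosomal protein and nuclear-retained RNAs, synapse and neurotrophin genes, and markers of the cell types and neighbouring regions that a cortex dissection can hold. A list was tested with at least 5 kept members, which left 28, and 3 were too small. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The named genes were Ercc6 and Ndn, genes past the threshold, up to 8 per direction with the smallest unadjusted p among genes with a mean FPKM of at least 1 in the higher group and groups that did not overlap, and up to 4 members per list with the smallest p. Predicted genes without a common symbol and pseudogenes were counted but not named. No exact permutation test was used, because 2 libraries against 2 cannot reach the threshold.

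Alternatives were a pseudocount of 0.1, no filter beyond 1 value above 0, a mean FPKM of at least 1, the replicate number as a block, only the 4 libraries compared, quantile normalization, trimmed-mean scaling, a fit without the mean-variance trend, a robust spread, and leaving out each library in turn. After seeing the data, limma-voom on the recovered reads, protein-coding genes of at least 200 bases and a weight per library were added. For changes that share libraries, the value without effects was simulated 100 times from the spread of each gene and group. After seeing the data, the fits with 1 library of the shCSB/shNDN pair were run on 100 such simulations.

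The steps were tested on simulated reads of 16254 genes with 100 genes changed 2-fold and 100 changed 4-fold. For shCSB against shControl, limma recovered 1 of the 2-fold and 81 of the 4-fold changes with 5 false calls, and limma-voom 15 and 96 with 0. For shCSB/shNDN against shCSB these were 10 and 76 with 11, and 22 and 90 with 4. For shCSB/shNDN against shControl they were 9 and 69 with 9, and 24 and 88 with 1. The simulated reads had 1 spread per group for all genes (dispersion 0.0135, 0.0202 and 0.0745), without differences between genes. Such recovery does not carry over to the data, where some changes above 4-fold did not pass, as given below. A low number of called genes thus does not exclude large changes. A synapse list raised 1.5-fold had a camera adjusted p of 2.89e-21, 3.64e-10 and 5.44e-19 in the 3 comparisons. With an estimated correlation these were 0.0432, 0.128 and 0.0511. Of 26 lists without a change, 0 were called. Genes were simulated as independent, while the estimated correlation in the data reached 0.96 for microglia markers. The simulation thus cannot tell how often unchanged lists are called in these data. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. No library was left out of the comparisons.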

Results

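RNA was sequenced from the primary visual cortex (V1) of 6 female C57BL mice aged 9 weeks that had received adeno-associated virus (AAV), a vector that carries hairpin genes into brain cells, in the same region. The libraries fall into 3 groups of 2: shControl with a control hairpin, shCSB with a hairpin against CSB, and shCSB/shNDN with hairpins against CSB and necdin. CSB is the product of Ercc6, a protein of transcription-coupled DNA repair whose loss causes Cockayne syndrome, a disorder of growth and the nervous system. Necdin is the product of Ndn, an imprinted gene expressed in neurons. The series title names hyperactive necdin as a marker of the neurological disease of Cockayne syndrome, so the design asks what the CSB hairpin changes and what the added Ndn hairpin does to that change. The deposited FPKM values correspond to 15731788 to 17365285 reads per library.

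Libraries of a group did not lie uniformly closer to each other than to other groups. On log2(FPKM + 1) over 16254 genes, Pearson's r across genes, which are not independent replicates, was 0.986 between the 2 shControl libraries, 0.980 between the 2 libraries labelled shCSB and 0.939 between the 2 labelled shCSB/shNDN. Each library labelled shCSB/shNDN correlated better with every library of the other groups, at 0.944 to 0.957, than with its own replicate. Replicate 1 of shCSB correlated with replicate 1 of shControl at 0.985, about as closely as the control libraries with each other. The first principal component, with 41.0% of the variance, placed the libraries labelled shCSB/shNDN at 25.0 and 46.3, away from the control libraries at -24.5 and -23.4, and the second, with 31.2%, set them apart from each other at -45.6 and 31.9. Replicate 2 of shCSB/shNDN also differed in its reads. Mitochondrially encoded genes took 1.41% of them, against 4.95% to 7.65% in the other libraries, and 434 genes had exactly 1 read, against 1595 to 1837.

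Ercc6 did not show the loss that the labels name, and Ndn lay well below the other libraries in 1 of the 2 labelled shCSB/shNDN. Ercc6 (ENSMUSG00000054051, GRCm38 chromosome 14, 32513521 to 32580990) had FPKM values of 1.46 and 1.22 in shControl, 1.29 and 1.61 in the libraries labelled shCSB, and 1.61 and 1.81 in those labelled shCSB/shNDN, each resting on 235 to 399 reads. Its log2 change was 0.066 ± 0.18 (SE) for shCSB against shControl, with a 95% interval from -0.36 to 0.49, and 0.21 ± 0.18 for shCSB/shNDN against shControl (limma adjusted p = 1 and 0.637). The first of these changes turned to -0.0059 without shControl replicate 2 and to -0.029 without shCSB replicate 2. On the scale of the recovered reads, the level in the libraries labelled shCSB was 108% of that in shControl, with a 95% interval from 74.0% to 158%. Because Ercc6 showed no loss, groups are named below as libraries labelled shCSB or shCSB/shNDN. Every direction drawn from them rests on labels that this gene does not bear out.

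Ndn (ENSMUSG00000033585, GRCm38 chromosome 7, 62346569 to 62350262) was not higher in the libraries labelled shCSB, where its FPKM was 47.9 and 38.1, than in shControl, where it was 56.1 and 49.8. The log2 change was -0.30 ± 0.39 (SE, limma adjusted p = 1), with a 95% interval from -1.24 to 0.64. In the libraries labelled shCSB/shNDN, Ndn was 16.8 in replicate 1 and 41.0 in replicate 2, and the second value lay between the 2 values of shCSB. The change against shCSB was -0.68 ± 0.39, with a 95% interval from -1.62 to 0.26, and that against shControl -0.98 ± 0.39, with one from -1.92 to -0.036 that leaves out 0 (adjusted p = 0.686 and 0.362). On the scale of the recovered reads, the level was 49.7% of that in shControl, with a 95% interval from 27.7% to 89.1%. With replicate 1 as the only library of its group, that is without shCSB/shNDN replicate 2, these changes were -1.30 and -1.60 and passed the threshold, in a kind of fit that also passes many genes of simulated unchanged groups, as given below. Without shCSB/shNDN replicate 1 they were -0.060 and -0.36 and did not.

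**Figure D1:**
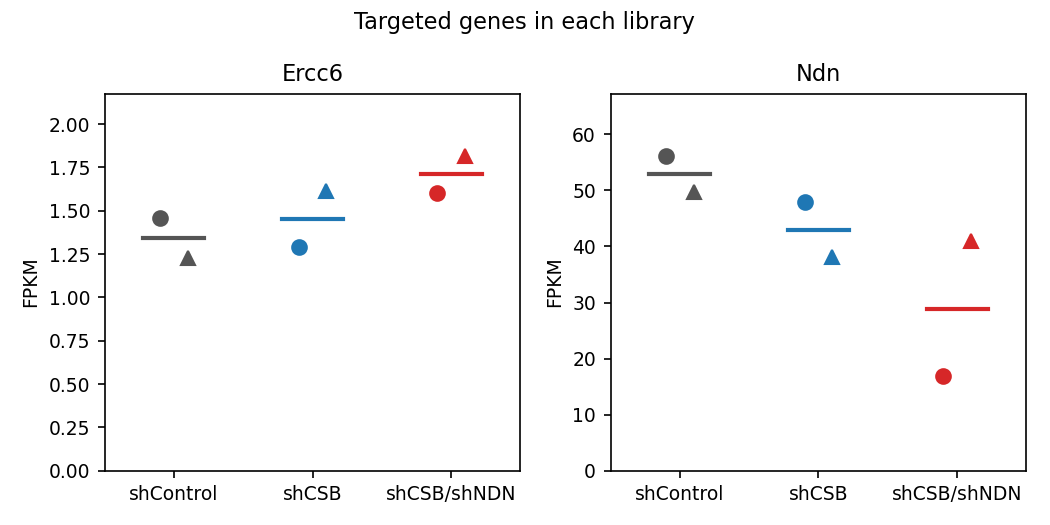
FPKM of Ercc6 (left) and Ndn (right) in each of the 6 libraries, with replicate 1 as circles, replicate 2 as triangles and group means as bars. Ercc6 lies between 1.22 and 1.81 with 1.29 and 1.61 in the libraries labelled shCSB against 1.46 and 1.22 in shControl, and Ndn is lowest at 16.8 in shCSB/shNDN replicate 1.

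In the libraries labelled shCSB, compared with shControl, genes of interferon response, antigen presentation, meningeal fibroblasts and reactive astrocytes lay higher as lists with the preset correlation of camera, and 0 of 28 lists passed with an estimated correlation (smallest adjusted p = 0.731). Lists that lay lower, of immediate early, myelin, respiratory chain and ribosomal protein genes, each lost the call without 1 or more of the libraries. List medians lay between -0.28 and 0.63 on the scale of log2(FPKM + 1). With a pseudocount of 0.1 or by limma-voom some were larger, up to 1.46 for lymphocytes. No single gene passed the threshold. With limma, 0 of 16254 genes had an adjusted p under 0.05, against 316 at an unadjusted p under 0.05 where chance gives 813. On the recovered reads, limma-voom gave 0 and 179. Genes are correlated, and how far such counts stray from 813 by chance was not tested, here and in the comparisons below. The 316 rests on a spread pooled with the shCSB/shNDN pair, and it was 896 with only the 4 libraries compared and 890 with a weight per library, each above 813. It was 165 without shControl replicate 2 and 169 without shCSB replicate 2. Among the 28 lists tested, 9 rose and 4 fell in the camera test with the preset correlation. With an estimated correlation or in the fry test, 0 passed. That correlation was estimated over all 6 libraries, so it includes the spread of the shCSB/shNDN pair and is the same in all comparisons. It was not estimated from the 4 libraries compared alone.

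Interferon-induced genes rose as a list, with a median of 0.55, all 27 members above 0 and 25 with both libraries above both controls (camera adjusted p = 2.08e-12, adjusted p = 0.731 with an estimated correlation). Ifi27 had FPKM values of 27.0 and 28.5 in shControl and 41.5 and 44.4 in shCSB, a change of 0.61 ± 0.16 (SE). The guanylate-binding protein gene Gbp3 was at 1.37 and 1.15 against 2.34 and 3.79, and the chemokine gene Cxcl10 at 0.0273 and 0.0297 against 1.14 and 1.30. Antigen presentation genes rose as a list with a median of 0.63 over 17 members (adjusted p = 1.75e-07, adjusted p = 0.731 with an estimated correlation). H2-Q6, a class I gene whose reads can be shared with close H2 paralogs, had a log2 change of 1.53 ± 0.38, and Cd74, the invariant chain of class II, one of 1.39 ± 0.55, without passing the threshold. Reactive astrocyte genes had a median of 0.36 over 15 members (adjusted p = 6.66e-06, adjusted p = 0.731 with an estimated correlation), and one of 0.22 without shCSB replicate 2. Complement C4b was at 3.89 and 2.09 in shControl against 9.42 and 11.3, and the intermediate filament gene Vim had a log2 change of 0.80 ± 0.31. None of these 3 lists had a member past the threshold, over all genes tested or adjusted over the list alone.

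Microglia markers rose as a list with a median of 0.29 over 20 members (adjusted p = 0.00476, adjusted p = 0.791 with an estimated correlation), and the call ended without shCSB replicate 2 (median 0.18, adjusted p = 0.174). The protease gene Ctss was at 41.8 and 48.4 against 70.4 and 79.9, and Siglech at 3.19 and 2.69 against 4.29 and 5.23. Activated microglia genes had a median of 0.17 over 20 members (adjusted p = 0.0385, adjusted p = 0.816 with an estimated correlation). Lysozyme Lyz2 in that list was at 4.57 and 4.22 against 12.4 and 14.5. That call ended, at medians no smaller, without shControl replicate 1 (0.18, adjusted p = 0.130) or replicate 2 (0.19, 0.0507), without shCSB replicate 1 (0.21, 0.173) or replicate 2 (0.20, 0.0968), with no filter on low values (0.17, 0.189) and with a robust spread (0.17, 0.0535). Neither list had a member past the threshold on either count. T and B lymphocyte markers had a median of 0.29 over 11 members (adjusted p = 0.0241, adjusted p = 0.731 with an estimated correlation), with 0 members past the threshold over all genes and 2 up when adjusted over the list alone. The immunoglobulin genes Igkc, with a log2 change of 5.20 ± 1.29 (SE), and Jchain, at 0.293 and 0.213 against 5.72 and 2.21, led it. It was no longer called without shControl replicate 1 (median 0.29, adjusted p = 0.0996), without shCSB replicate 2 (0.12, 0.115) or with no filter on low values (0.027, 0.332).

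Meningeal and fibroblast markers, which a cortex dissection can carry, had the smallest camera p of this comparison. All 15 members lay above 0, with a median of 0.62 (adjusted p = 5.05e-18, adjusted p = 0.731 with an estimated correlation), 0 past the threshold over all genes and 7 adjusted over the list alone. Among the 8 genes with the smallest p in the upward direction were Ogn, coding for a matrix proteoglycan, at 0.981 and 0.835 against 2.78 and 2.56, and Aldh1a2, a retinoic acid synthesis gene of the meninges, at 1.55 and 1.12 against 4.04 and 3.33. Slc13a4 had a log2 change of 0.88 ± 0.24 (SE) and Crabp2 one of 0.62 ± 0.19. The rest of these 8 were Islr (1.06 ± 0.23), Slc6a20a (0.85 ± 0.18), Slc47a1 (1.06 ± 0.23), Srp54b (0.97 ± 0.17), the microRNA locus Mir7220, and the immunoglobulin segment Igkv4-53. Igkv4-53 was listed at 0 in both controls and at 84.0 and 9.65 in shCSB, and passed the threshold without shCSB replicate 2. Srp54b has near-identical copies, so its reads are uncertain. Endothelial and mural markers, such as Tek (0.34 ± 0.18) and Acta2 (0.29 ± 0.16), had a median of 0.11 over 18 members, 0 past the threshold on either count (adjusted p = 0.0265, adjusted p = 0.731 with an estimated correlation), and lost the call without shControl replicate 1 (median 0.16, adjusted p = 0.130), shControl replicate 2 (0.12, 0.0507) or shCSB replicate 2 (0.039, 0.792), and with no filter (0.12, 0.0742). Nuclear-retained long noncoding RNAs had a median of 0.17 over 12 members, 0 past the threshold on either count (adjusted p = 0.00476, adjusted p = 0.731 with an estimated correlation). Neat1 was at 4.07 and 4.01 against 5.93 and 6.64, and Xist at 9.24 and 6.88 against 10.3 and 16.0. Without shCSB replicate 2 this call ended (median 0.082, adjusted p = 0.450).

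Immediate early genes, which neuronal activity induces, fell as a list with a median of -0.28 over 24 members (adjusted p = 0.00156, adjusted p = 0.731 with an estimated correlation), with 0 past the threshold over all genes and 1 adjusted over the list alone. Arc was at 276 and 321 in shControl against 138 and 104, Ier2 at 43.8 and 39.0 against 19.4 and 16.8, and Dusp1 at 41.3 and 39.0 against 19.7 and 20.2. Homer1 in the same list had a positive change of 0.88 ± 0.26 (SE). The call ended without shControl replicate 1 (median -0.17, adjusted p = 0.118) and without shCSB replicate 2, where the median was 0.029 (adjusted p = 0.688). Myelin genes fell as a list with a median of -0.27 over 19 members (adjusted p = 0.000283, adjusted p = 0.731 with an estimated correlation), but not without shCSB replicate 1 (median -0.13, adjusted p = 0.619). Mog was at 56.6 and 57.3 against 37.8 and 50.2, and Fa2h at 19.2 and 17.9 against 12.9 and 15.1. Nuclear-encoded respiratory chain genes had a median of -0.15 over 49 members (adjusted p = 0.000555, adjusted p = 0.734 with an estimated correlation), with Cycs at -0.36 ± 0.23 and Cox5a at -0.23 ± 0.20. This rested on shCSB replicate 2, without which the test pointed upward (median -0.00085, adjusted p = 0.879), and it was lost under quantile normalization (median -0.029, adjusted p = 0.618). Cytosolic ribosomal protein genes had a median of -0.11 over 62 members (adjusted p = 0.0154, adjusted p = 0.791 with an estimated correlation), which turned to 0.013 under quantile normalization and lost the call without shControl replicate 1 (median -0.060, adjusted p = 0.495) or shCSB replicate 2 (-0.057, 0.469). Rpl24 and Rpl13a, members with many processed copies in the genome, had log2 changes of -0.42 ± 0.20 and -0.29 ± 0.17. None of these last 3 lists had a member past the threshold on either count. The 8 genes with the smallest p in the downward direction were Mir6929, Mir7049, Mir5620, Mir7004, Lsm5 (-1.71 ± 0.30), Ier2 (-1.15 ± 0.23), Dusp23 (-0.81 ± 0.19) and Gpr25 (-1.05 ± 0.26), of which the microRNA loci had few reads. Mir6929, for example, had 7 and 7 reads in shControl against 1 and 1.

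Medians also moved by over 1.5 times where the call stayed. With a pseudocount of 0.1 and by limma-voom, they were 0.91 and 1.17 for interferon-induced genes, 0.94 and 0.98 for antigen presentation, 0.57 and 0.56 for reactive astrocytes, 1.02 and 1.13 for meninges and fibroblasts, and 1.23 and 1.46 for lymphocytes. Reactive astrocyte genes were at 0.22 with no filter on low values, and under quantile normalization activated microglia genes were at 0.25 and myelin genes at -0.15. In the fit without shCSB replicate 1, medians were -0.50 for immediate early genes, 0.58 for lymphocytes, 0.23 for endothelial and mural cells, -0.29 for the respiratory chain, -0.18 for ribosomal proteins and 0.29 for nuclear-retained RNAs. Ribosomal protein genes were at -0.19 without shControl replicate 2, and myelin genes at -0.41 without shCSB replicate 2.

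Of the remaining 15 lists, none was called. Their medians were 0.067 for other imprinted genes, 0.014 for nucleotide excision repair, 0.058 for p53 targets, 0.0049 for E2F and cell cycle genes, -0.040 for stress response, 0.095 for astrocytes, -0.13 for oligodendrocyte precursors, -0.10 for excitatory neurons, -0.100 for inhibitory neurons, -0.050 for synapse genes, 0.011 for neurotrophin and axon guidance genes, -0.19 for blood cells, -0.11 for hippocampus, 0.034 for striatum and thalamus, and -0.19 for mitochondrially encoded genes. For nucleotide excision repair, the pathway in which CSB acts, the mean was -0.014 and opposite in sign to the median, as was the mean of -0.034 for striatum and thalamus. Ercc5 (0.39 ± 0.16, SE) and Ercc2 (-0.35 ± 0.17) had opposite signs. The number of genes past the threshold was 1 without shCSB replicate 2, 1 without shCSB/shNDN replicate 1 and 1 without shCSB/shNDN replicate 2.

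**Figure D2:**
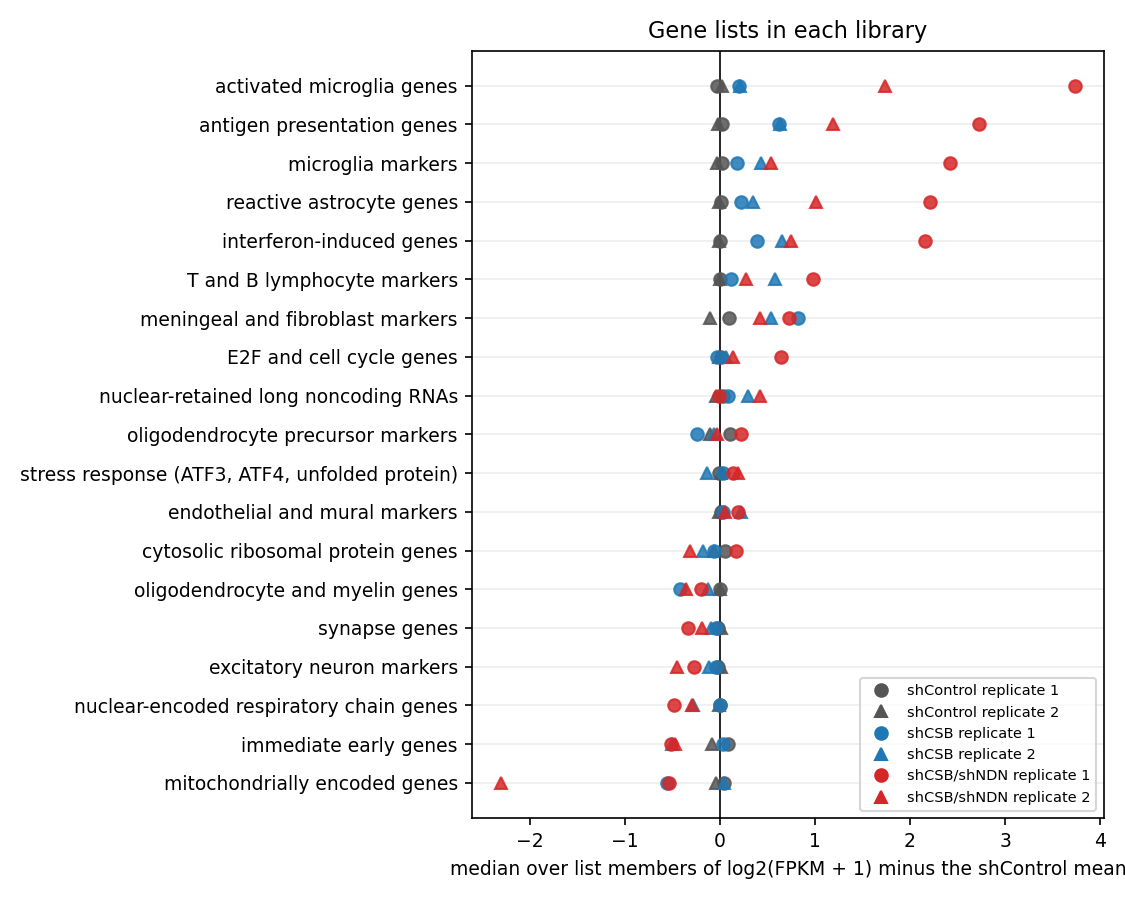
Median over the members of each gene list of log2(FPKM + 1) minus the mean of the shControl libraries, for each library (circles replicate 1, triangles replicate 2) and each list called in at least 1 comparison. Activated microglia genes reach 3.74 in shCSB/shNDN replicate 1 and 1.74 in replicate 2, and mitochondrially encoded genes reach -2.30 in replicate 2.

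Microglial, antigen presentation, interferon and reactive astrocyte genes lay well above the libraries labelled shCSB in those labelled shCSB/shNDN, and mitochondrially encoded, respiratory chain, synapse and excitatory neuron genes lay below. These calls rest on the preset correlation, 0 of 28 lists passed with an estimated correlation (smallest adjusted p = 0.436), and the interferon list and the 4 lower lists each lost the call without 1 or more of the libraries. This comparison asks what the Ndn hairpin adds. The activated microglia list had the largest median at 2.59. With limma, 0 of 16254 genes passed, against 1371 at an unadjusted p under 0.05 where chance gives 813, and the smallest adjusted p was 0.273. The 1371 became 849 with only the 4 libraries compared and 864 with a weight per library, each above 813. It was also lower without any 1 of the shControl or shCSB libraries. It became 4448 and 2289 without shCSB/shNDN replicate 1 and 2. limma-voom gave 0 genes, and 1383 at an unadjusted p under 0.05. Camera with the preset correlation called 8 lists up and 4 down, while 0 passed with an estimated correlation or in the fry test.

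The 2 libraries labelled shCSB/shNDN differed from each other, and the counts moved with them. Without shCSB/shNDN replicate 2, so with replicate 1 alone, 465 genes passed upward and 19 downward against shCSB, and without shCSB/shNDN replicate 1, with replicate 2 alone, 374 upward and 519 downward. A group of 1 library is assumed in these fits to vary like the other groups, which the shCSB/shNDN pair did not. In 100 simulations of unchanged groups with the spread of these, such fits passed a mean of 558 genes upward and 548 downward with replicate 1 alone, and 563 and 544 with replicate 2 alone. The observed counts do not exceed these. Both fits passed 92 genes upward, where independent lists would share 10.7, and 5 downward, where they would share 0.607. Another 7 were up with replicate 1 and down with replicate 2, and 1 the reverse. Unchanged groups that share the same shCSB libraries gave a mean of 108 upward and 106 downward in both fits, and with lists of the observed sizes 72.8 (at most 95) and 6.68 (at most 12). The shared numbers thus did not exceed the highest simulated ones, which does not decide whether there was an effect. The simulated spread takes the difference between replicates of each gene as noise, so an effect of unequal size in the 2 libraries enters it. The downward count with replicate 1 alone lay far below the simulated mean, so the simulation did not match these data throughout. The 92 included 12 of the 20 activated microglia genes, 8 of the 20 microglia markers, 5 of the 17 antigen presentation genes and 4 of the 15 reactive astrocyte genes. Without shCSB replicate 2, 1 gene passed.

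Activated microglia genes rose as a list, with 19 of 20 members above 0 (camera adjusted p = 9.63e-22, adjusted p = 0.436 with an estimated correlation), 0 past the threshold over all genes and 17 adjusted over the list alone. The secreted phosphoprotein gene Spp1 was at 7.82 and 3.27 in shCSB against 451 and 96.5, the lysosomal protease gene Ctsd at 148 and 163 against 2161 and 808, and the galectin gene Lgals3 had a log2 change of 3.91 ± 0.58 (SE). Microglia markers had a median of 1.40 (adjusted p = 4.15e-12, adjusted p = 0.497 with an estimated correlation), with 10 of 20 adjusted over the list alone and 0 over all genes. Trem2, a microglial receptor gene, was at 6.37 and 7.57 against 80.4 and 34.1, Fcrls at 12.4 and 12.6 against 156 and 58.2, and Aif1 had a log2 change of 1.72 ± 0.33. Antigen presentation genes had a median of 1.17 (adjusted p = 9.17e-14, adjusted p = 0.471 with an estimated correlation), with 12 of 17 adjusted over the list alone and 0 over all genes. Cd74 had a log2 change of 3.54 ± 0.55 (SE), the class II genes H2-Ab1 one of 2.87 ± 0.53 and H2-Eb1 one of 2.66 ± 0.52, and Tapbp one of 1.14 ± 0.23. Reactive astrocyte genes had a median of 1.15 (adjusted p = 4.15e-12, adjusted p = 0.436 with an estimated correlation), with 9 of 15 adjusted over the list alone and 0 over all genes. Vim had a log2 change of 2.08 ± 0.31 (SE), and Timp1, an inhibitor of matrix proteases, was at 0.894 and 1.33 against 5.48 and 3.55. The medians of these 4 lists were lower without shCSB/shNDN replicate 1, at 1.54 for activated microglia genes, 0.41 for microglia markers, 0.63 for antigen presentation and 0.64 for reactive astrocytes, and the calls with the preset correlation stayed. The median of microglia markers was 2.13 and that of antigen presentation 1.89 without shCSB/shNDN replicate 2. Astrocyte markers as such had a median of -0.052.

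Interferon-induced genes had a median of 0.75 over 27 members, all above 0 (adjusted p = 7.16e-12, adjusted p = 0.497 with an estimated correlation), with 4 adjusted over the list alone and 0 over all genes. Oas1a had a log2 change of 2.11 ± 0.36, Psmb8 was at 2.28 and 1.87 against 13.9 and 6.26, and Bst2 at 14.1 and 14.0 against 98.6 and 32.2. Without shCSB/shNDN replicate 1 the median was 0.21 and the call ended (adjusted p = 0.0547). E2F and cell cycle genes had a median of 0.40 over 21 members, 0 past the threshold on either count (adjusted p = 5.65e-05, adjusted p = 0.497 with an estimated correlation), and the same library decided it (median 0.11, adjusted p = 0.351 without it). Ccnb2 had a log2 change of 0.84 ± 0.25 (SE), Aurkb one of 0.67 ± 0.22 and Mcm6 one of 0.52 ± 0.18. Stress response genes had a median of 0.25 over 22 members (adjusted p = 0.00196, adjusted p = 0.436 with an estimated correlation), with 1 adjusted over the list alone and 0 over all genes, and lost the call without shCSB replicate 2 (median 0.12, adjusted p = 0.0855) or shCSB/shNDN replicate 1 (0.19, 0.0513). Atf3, a transcription factor gene induced by stress, was at 0.425 and 0.522 against 10.8 and 4.86. Oligodendrocyte precursor markers had a median of 0.097 over 13 members (adjusted p = 0.0327, adjusted p = 0.512 with an estimated correlation), with 1, Matn4 (0.74 ± 0.15), adjusted over the list alone and 0 over all genes. That call ended without shCSB replicate 1 (median -0.010, adjusted p = 0.357), without shCSB/shNDN replicate 1 (0.083, 0.843) and with a weight per library (0.097, 0.0646). Among the genes with the smallest p in the upward direction were Gpsm3, Hcls1, Ube2l6, Cyba, Tmem176a, Lyz2 and Atf3, with changes from 1.18 ± 0.16 for Tmem176a to 4.11 ± 0.55 for Lyz2. Hcls1 and Cyba, genes of blood-lineage cells and of the phagocyte oxidase, had log2 changes of 2.07 ± 0.25 and 2.47 ± 0.32.

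Mitochondrially encoded genes fell as a list with a median of -1.07 over 15 members (adjusted p = 5.12e-05, adjusted p = 0.497 with an estimated correlation), with 1 adjusted over the list alone and 0 over all genes. mt-Nd1 was at 6364 and 10117 in shCSB against 5922 in replicate 1 and 978 in replicate 2 of shCSB/shNDN, and mt-Nd3 at 126 and 128 against 65.8 and 62.5. The median was -2.30 without shCSB/shNDN replicate 1, and -0.21 without shCSB/shNDN replicate 2, where the call ended (adjusted p = 0.185). Nuclear-encoded respiratory chain genes had a median of -0.27 over 49 members (adjusted p = 8.83e-06, adjusted p = 0.497 with an estimated correlation), and lost the call without shCSB replicate 1 (median -0.16, adjusted p = 0.0679) or shCSB/shNDN replicate 1 (-0.17, 0.134). Cox7b had a log2 change of -0.82 ± 0.27 (SE) and Cox6c one of -0.51 ± 0.19. Synapse genes had a median of -0.20 over 30 members (adjusted p = 0.00161, adjusted p = 0.436 with an estimated correlation), lost without shCSB/shNDN replicate 1 at a median of -0.18 (adjusted p = 0.128). The glutamate receptor gene Gria1 had a log2 change of -0.53 ± 0.21 and Snap25, of the vesicle fusion complex, one of -0.58 ± 0.27. Excitatory neuron markers had a median of -0.20 over 20 members (adjusted p = 0.0132, adjusted p = 0.436 with an estimated correlation), and neither library alone kept the call, though the medians were no smaller in size (-0.38, adjusted p = 0.0802 without shCSB/shNDN replicate 1 and -0.25, adjusted p = 0.0896 without shCSB/shNDN replicate 2). Neurod6 had a log2 change of -0.86 ± 0.32 and Fezf2, a gene of deep-layer neurons, one of -0.96 ± 0.38. None of these last 3 lists had a member past the threshold on either count. Besides mt-Nd3, the genes with the smallest p in the downward direction were Snord42b (-1.43 ± 0.22), mt-Ti (-2.77 ± 0.47), the metallothionein gene Mt2 (-1.20 ± 0.20), Igkv4-53, Tmem169 (-0.81 ± 0.15), Cyp2j12 (-0.92 ± 0.17) and the potassium channel gene Kcng1 (-0.72 ± 0.16).

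Other medians moved by over 1.5 times with the call kept. For interferon-induced genes the median was 1.40 without shCSB/shNDN replicate 2. E2F and cell cycle genes were at 0.61 without that library, 0.69 with a pseudocount of 0.1, 0.77 by limma-voom and 0.25 when a mean FPKM of 1 was required. Oligodendrocyte precursor markers were at 0.30 without shCSB replicate 2, 0.27 without shCSB/shNDN replicate 2, 0.24 when a mean FPKM of 1 was required and 0.054 under quantile normalization. Stress response genes were at 0.15 without shCSB/shNDN replicate 2, and without shCSB replicate 2 respiratory chain genes were at -0.43 and mitochondrially encoded genes at -0.64.

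The other 16 lists were not called. Their medians were -0.050 for other imprinted genes, 0.018 for nucleotide excision repair, 0.12 for p53 targets, -0.18 for immediate early genes, 0.040 for lymphocytes, -0.052 for astrocytes, 0.038 for myelin, -0.053 for inhibitory neurons, -0.11 for neurotrophin and axon guidance genes, -0.026 for endothelial and mural cells, -0.16 for meninges and fibroblasts, 0.083 for blood cells, -0.13 for hippocampus, 0.0080 for striatum and thalamus, 0.025 for ribosomal proteins and 0.034 for nuclear-retained RNAs. The p53 target Ccng1 had a log2 change of 0.45 ± 0.15 (SE).

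The libraries labelled shCSB/shNDN differed most from shControl, and the 5 lists with the largest medians were those that led against shCSB. Both comparisons share the shCSB/shNDN libraries, so this is no independent support. Activated microglia genes had a median of 2.90, antigen presentation genes 2.00, microglia markers 1.67, reactive astrocyte genes 1.61 and interferon-induced genes 1.29, while mitochondrially encoded, immediate early, respiratory chain, excitatory neuron and synapse genes lay below the controls. The first 5 medians without shCSB/shNDN replicate 1 were 1.74, 1.19, 0.54, 1.01 and 0.75, so replicate 1 carried much of their size. Their calls with the preset correlation stayed, and with all libraries 0 of 28 lists passed with an estimated correlation (smallest adjusted p = 0.362). With limma, 1 of 16254 genes passed, the microRNA locus Mir6929, which fell (adjusted p = 0.0176), against 2180 at an unadjusted p under 0.05, a number that became 861 and 891 without shControl replicate 1 and 2 and 5136 without shCSB/shNDN replicate 1. Mir6929 had 7, 7, 1, 1, 0 and 0 reads in the 6 libraries, and it did not pass without any 1 of the 4 shControl and shCSB libraries (adjusted p = 0.301 to 0.561). On the recovered reads, limma-voom gave 0 genes with 2254 at an unadjusted p under 0.05. The moderated F test over the 3 groups also passed 1 gene, Mir6929 again (adjusted p = 0.0496), against 1378 at an unadjusted p under 0.05 and 0 by limma-voom. The 1378 became 649 and 656 without shControl replicate 1 and 2, and 4167 and 2270 without shCSB/shNDN replicate 1 and 2.

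Without shCSB/shNDN replicate 2, 583 genes passed upward and 45 downward against shControl, and without shCSB/shNDN replicate 1, 750 upward and 1058 downward, under the same assumption on a group of 1 library. Simulated unchanged groups gave a mean of 533 upward and 519 downward with replicate 1 alone, and 534 and 518 with replicate 2 alone (at most 659 and 613). Both fits shared 180 upward genes, where independent lists would share 26.9, and 17 downward, where they would share 2.93, and 10 genes were up with replicate 1 and down with replicate 2 and 1 the reverse. Unchanged groups sharing the controls gave a mean of 98.7 upward (at most 134) and 95.8 downward, and with lists of the observed sizes 130 (at most 163) and 16.9. The upward number lay above the highest simulated values and the downward number did not. Genes were simulated as independent, here and against shCSB, while the estimated correlation in the data reached 0.96 for microglia markers. Correlated genes pass together, so the highest simulated values cannot tell whether the upward number exceeds that of unchanged groups. Part of the excess may also come from the shared controls, where the simulation understates their spread. The limit of the simulated spread given above holds here too. The 180 held 15 of 20 activated microglia genes, 11 of 17 antigen presentation genes, 9 of 20 microglia markers, 9 of 27 interferon-induced genes and 8 of 15 reactive astrocyte genes. The microglial members included Aif1, Ctss, Fcrls and Trem2.

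Camera called 9 lists up and 5 down with the preset correlation and 0 with an estimated correlation or in the fry test. Activated microglia genes rose (adjusted p = 8.31e-19, adjusted p = 0.362 with an estimated correlation), with 18 of 20 members adjusted over the list alone and 0 over all genes. Spp1 had a log2 change of 5.99 ± 0.71 (SE), Lgals3 one of 4.36 ± 0.58 and Lyz2 one of 5.53 ± 0.55, Lyz2 reading 4.57 and 4.22 against 477 and 129. Antigen presentation genes (adjusted p = 2.97e-16, adjusted p = 0.362 with an estimated correlation) had 13 of 17 members adjusted over the list alone and 0 over all genes. H2-Ab1 was at 0.413 and 0.368 against 35.4 and 9.74, Cd74 had a log2 change of 4.93 ± 0.55 and H2-Q6 one of 2.94 ± 0.38. Microglia markers (adjusted p = 3.71e-13, adjusted p = 0.366 with an estimated correlation) had 12 of 20 adjusted over the list alone and 0 over all genes, with Trem2 at 3.06 ± 0.38, Fcrls at 2.90 ± 0.42 and Ctss at 2.80 ± 0.45. Reactive astrocyte genes (adjusted p = 5.43e-14, adjusted p = 0.362 with an estimated correlation) had 12 of 15 adjusted over the list alone and 0 over all genes, with Vim at 2.87 ± 0.31, Timp1 at 1.96 ± 0.23 and C4b at 2.70 ± 0.40. Interferon-induced genes (adjusted p = 2.06e-18, adjusted p = 0.362 with an estimated correlation) had 19 of 27 adjusted over the list alone and 0 over all genes, with Ifi27 at 1.11 ± 0.16, Psmb8 at 2.24 ± 0.33 and Cxcl10 at 2.84 ± 0.42.

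**Figure D3:**
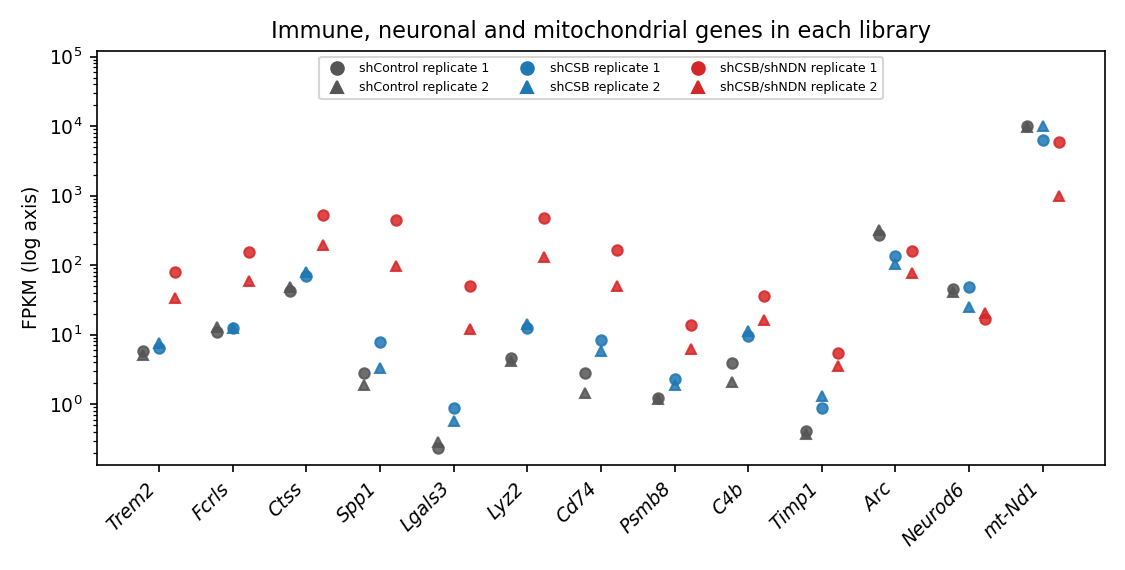
FPKM on a log axis of 13 genes in each library, with colours for the 3 groups, circles for replicate 1 and triangles for replicate 2. The microglial and antigen presentation genes are higher in both libraries labelled shCSB/shNDN and highest in replicate 1, as for Trem2 with 80.4 and 34.1, and mt-Nd1 is lowest at 978 in replicate 2.

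T and B lymphocyte markers had a median of 0.70 over 11 members (adjusted p = 0.00809, adjusted p = 0.362 with an estimated correlation), lost without shCSB/shNDN replicate 1 (median 0.28, adjusted p = 0.286) or when a mean FPKM of 1 was required (1.06, 0.165), with Jchain at 1.41 ± 0.49 (SE) and Nkg7, a gene of cytotoxic lymphocytes, listed at 0 in both controls and at 0.833 and 0.831 in shCSB/shNDN. None of its members passed over all genes or adjusted over the list alone. Meningeal and fibroblast markers had a median of 0.65 over 15 members, all above 0 (adjusted p = 2.00e-07, adjusted p = 0.362 with an estimated correlation), with 6 adjusted over the list alone and 0 over all genes, and one of 0.42 without shCSB/shNDN replicate 1. Igfbp2 was at 30.3 and 31.9 against 61.2 and 94.5, and the collagen gene Col1a2 at 0.563 and 0.453 against 1.47 and 2.01. E2F and cell cycle genes had a median of 0.33 over 21 members (adjusted p = 0.000257, adjusted p = 0.413 with an estimated correlation), and stress response genes one of 0.11 over 22 members (adjusted p = 0.0175, adjusted p = 0.362 with an estimated correlation). Both calls ended without shCSB/shNDN replicate 1, where the medians were 0.14 and 0.20 (adjusted p = 0.286 and 0.0767), lower for the first and higher for the second. Mcm6 had a log2 change of 0.68 ± 0.18 and Atf3 one of 2.47 ± 0.33, Atf3 being the 1 stress gene past the threshold when adjusted over the list alone, against 0 of the cell cycle genes and 0 of either list over all genes. Among the genes with the smallest p in the upward direction were Lyz2, Cyba, Vim, Hcls1, Cd74, Gpsm3 and Cdkn2a. Cdkn2a, which codes for inhibitors of the cell cycle, was at 0.210 and 0.114 in shControl, 0.781 and 0.431 in shCSB, and 3.40 and 2.74 in shCSB/shNDN, a change of 1.81 ± 0.21 (limma adjusted p = 0.101).

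Mitochondrially encoded genes fell as a list with a median of -1.12, all 15 members below 0 (adjusted p = 1.87e-05, adjusted p = 0.413 with an estimated correlation), and without shCSB/shNDN replicate 1 or 2 the median was -2.30 or -0.53. mt-Nd3 had a log2 change of -1.05 ± 0.17 (SE), the 1 member past the threshold when adjusted over the list alone, and mt-Nd1 one of -2.03 ± 0.82. Respiratory chain genes had a median of -0.42 over 49 members (adjusted p = 7.25e-09, adjusted p = 0.366 with an estimated correlation), with Cox7b at -1.06 ± 0.27, Cox6c at -0.74 ± 0.19 and Ndufa4 at -0.96 ± 0.30. Immediate early genes had a median of -0.56 over 24 members (adjusted p = 0.00738, adjusted p = 0.366 with an estimated correlation), lost without shCSB/shNDN replicate 1 (median -0.47, adjusted p = 0.0758) and kept without shControl replicate 1 at a median of -0.23 (adjusted p = 0.0398), with Arc at -1.42 ± 0.37, Nr4a1 at -1.16 ± 0.31 and Gadd45b at -0.99 ± 0.28. Excitatory neuron markers had a median of -0.27 over 20 members (adjusted p = 0.00652, adjusted p = 0.362 with an estimated correlation), and one of -0.44 without shCSB/shNDN replicate 1. Neurod6 was at 46.1 and 41.0 against 17.0 and 20.4, Fezf2 at 30.5 and 18.4 against 9.83 and 7.94, and Rbp4 at 22.1 and 17.9 against 11.6 and 8.20. Synapse genes had a median of -0.25 over 30 members (adjusted p = 0.00172, adjusted p = 0.362 with an estimated correlation), lost without shCSB/shNDN replicate 1 (median -0.19, adjusted p = 0.0758) and under quantile normalization (median -0.11, adjusted p = 0.0649). Dlg4, a postsynaptic scaffold gene, was at 119 and 113 against 72.3 and 73.6, Shank1 at 104 and 112 against 78.5 and 47.9, and Vamp2 at 482 and 464 against 298 and 287. No member of the last 4 lists passed on either count. Besides Mir6929 and mt-Nd3, the genes with the smallest p in the downward direction were Mir7049, Mir5620, Cyp2j12 (-1.29 ± 0.17), Cabp7 (-1.72 ± 0.26), Cst6 (-1.14 ± 0.18) and Mt2 (-1.22 ± 0.20).

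Further medians moved by over 1.5 times with the call kept. With a pseudocount of 0.1 and by limma-voom they were 2.26 and 2.37 for interferon-induced genes, 0.67 and 0.75 for E2F and cell cycle genes, 1.65 and 1.86 for lymphocytes, and 1.08 and 1.12 for meninges and fibroblasts. Interferon-induced genes were at 2.16 and E2F and cell cycle genes at 0.65 without shCSB/shNDN replicate 2. With no filter on low values, reactive astrocyte genes were at 0.97 and lymphocytes at 0.22. Stress response genes were at 0.064 when a mean FPKM of 1 was required, and at 0.20 both under quantile normalization and without shControl replicate 1, and respiratory chain genes at -0.27 under quantile normalization.

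The other 14 lists were not called. Their medians were -0.074 for other imprinted genes, -0.072 for nucleotide excision repair, 0.12 for p53 targets, 0.078 for astrocytes, -0.12 for myelin, 0.21 for oligodendrocyte precursors, -0.12 for inhibitory neurons, 0.0018 for neurotrophin and axon guidance genes, 0.081 for endothelial and mural cells, -0.029 for blood cells, -0.37 for hippocampus, 0.0041 for striatum and thalamus, -0.071 for ribosomal proteins and 0.31 for nuclear-retained RNAs. The neurotrophin list had a mean of -0.11 and the blood list one of 0.0037, each opposite in sign to its median, and for striatum and thalamus the test pointed down at a positive median. Within the p53 list, Dcxr had a log2 change of 0.90 ± 0.21 (SE). The hippocampal gene Spink8 was at 11.8 and 6.36 in shControl, 7.36 and 0.137 in shCSB, and 0.642 and 0 in shCSB/shNDN.

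If the added Ndn hairpin returned genes toward the control level, the change from shControl to shCSB and the change from shCSB to shCSB/shNDN would run against each other. Across 16254 genes, which are not independent replicates, Pearson's r between these changes was -0.024, where the shCSB libraries they share give -0.38 with no effect in 100 simulations. The covariance was -0.0026 against a simulated -0.034, a difference of 0.031. With the 2 shCSB libraries split between the changes, r was 0.14 and 0.28. The change from shControl to shCSB and that from shControl to shCSB/shNDN had r = 0.53 against a simulated 0.29 and a covariance of 0.068 against 0.024, and with split controls r was 0.31 and 0.25. The split changes share no library, but each part of a split holds 1, and their covariances were 0.018 and 0.044 for the first pair and 0.047 and 0.040 for the second. Where the simulation understates the spread of the shared controls, part of the excess in the second pair may come from them. No covariance of opposite sign, which a reversal across all genes would give, was present in any of these estimates after the simulated value was taken away. A covariance over all genes weighs most the genes that move most, so it cannot exclude a return of some genes. Ercc6 was not lower in shCSB, and Ndn lay in the range of shCSB in replicate 2 of shCSB/shNDN. These estimates therefore do not decide what a loss of Ndn does to a loss of CSB.

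CSB acts in the repair of transcribed genes, so gene length is a natural axis. Spearman's rho across genes between the log2 change and the gene length of the deposited table was 0.13 for shCSB against shControl, 0.045 for shCSB/shNDN against shCSB and 0.11 for shCSB/shNDN against shControl. In the first comparison the median change was -0.026 in the shortest of 5 equal bins, -0.062 in the next and 0.052 in the longest, so it did not rise evenly with length. The difference between replicates 2 and 1 of shCSB, which no treatment separates, gave a rho of 0.12, and those of shControl and shCSB/shNDN gave 0.033 and 0.038, so a replicate pair came close to the first value. Without shCSB replicate 2, the first value was 0.044. The second turned to -0.010 without shCSB replicate 1 and was 0.073 without shCSB replicate 2, 0.015 under quantile normalization and 0.030 with a mean FPKM of at least 1. With the genomic span of 13346 protein-coding genes instead, rho was 0.22, -0.068 and 0.056 in the 3 comparisons, so the second changed sign, and 0.21 between the replicates of shCSB.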

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

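Alternatives on the recovered reads (limma-voom), on protein-coding genes of at least 200 bases and with a weight per library were chosen after seeing the data, and the cause of the moves below was not tested. Of 39 list calls, each of 1 list in 1 comparison, 17 kept their call and direction under every alternative but the estimated correlation. Under that alternative, 0 lists passed in each comparison. A list called in several comparisons, which share libraries, counts in each. Named genes other than Ercc6 and Ndn gave 161 entries, each of 1 gene in 1 comparison. Of these, 77 kept their status and direction under all alternatives, and 0 reversed. Since only Mir6929 passed with the main settings, a kept status nearly always meant staying uncalled. Most changes of status were genes that passed only with 1 library of shCSB/shNDN. The median of ribosomal protein genes for shCSB against shControl turned to 0.013 under quantile normalization, and the respiratory chain median ranged from -0.29 to -0.00085 over the libraries left out, with the test reversed at the last value, without shCSB replicate 2. For shCSB against shControl, 2 genes passed with only the 4 libraries compared, 1 with a weight per library and 0 to 1 with each library left out. For shCSB/shNDN against shCSB, 0 to 893 genes passed with each library left out. For shCSB/shNDN against shControl, 3 genes passed with the replicate number as a block, 2 with a weight per library, 0 with no filter, with only the 4 libraries compared, by limma-voom and among protein-coding genes, and 0 to 1808 with each library left out. Deviations of equally numbered libraries correlated at 0.054, -0.071 and -0.016, so the numbers do not pair the libraries. In the F test, 0 genes passed with a pseudocount of 0.1, with no filter, with a mean FPKM of at least 1, with the block, under quantile normalization, by limma-voom and among protein-coding genes, 2 with a weight per library, and 0 to 596 with each library left out. The called lists numbered 8 to 13, 5 to 15 and 11 to 18 in the 3 comparisons with each library left out. The Ercc6 change for shCSB against shControl ranged from -0.029 to 0.16, and was -0.0059 without shControl replicate 2. The Ndn change ranged from -1.30 to -0.060 against shCSB and from -1.60 to -0.36 against shControl, past the threshold at the lower end of each, without shCSB/shNDN replicate 2. The covariance beyond the simulated one, of the change from shControl to shCSB with that from shCSB to shCSB/shNDN, was 0.069 with a pseudocount of 0.1 and 0.0183 with no filter. That of the change from shControl to shCSB with that from shControl to shCSB/shNDN was 0.107 with this pseudocount, 0.0255 with no filter, 0.050 with a mean FPKM of at least 1, 0.0365 under quantile normalization, and 0.0298 to 0.0565 with each library left out. The rho of gene length for shCSB against shControl ranged from 0.044 to 0.15. A library left alone in its group is assumed to vary like the other groups.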

Other observations

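Of the genes of the Prader-Willi cluster, the imprinted region that holds Ndn, 4 of 9 were kept, too few for a test. Besides Ndn, Snrpn was at 330 and 360 in shControl, 330 and 315 in the libraries labelled shCSB, and 208 and 407 in those labelled shCSB/shNDN. Ube3a was at 2.81 and 2.68, then 2.77 and 3.09, then 2.27 and 2.82, and Snhg14 had log2 changes of 0.22 ± 0.20 (SE) for shCSB against shControl and -0.02 ± 0.20 for shCSB/shNDN against shControl. None of them passed the limma threshold in any comparison. Of the choroid plexus markers, 1 of 13 was kept, the transthyretin gene Ttr, at 3.68 and 20.2 in shControl, 9.31 and 14.2 in shCSB, and 6.54 and 13.5 in shCSB/shNDN. Of the replication-dependent histone genes, 4 of 28 were kept. Hist1h1c was at 17.2 and 19.1 in shControl against 26.0 and 36.8 in shCSB/shNDN, and Hist1h2bc at 31.8 and 33.5 against 33.7 and 8.44.

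C1ql2, a marker of the hippocampus, which lies under the visual cortex, was at 11.1 and 3.52 in shControl, 6.53 and 0.281 in shCSB, and 0.967 and 3.10 in shCSB/shNDN. Of the haemoglobin transcripts, a sign of blood, Hbb-bs lay between 80.4 and 157 over the 6 libraries, Hba-a1 between 55.0 and 123, Hba-a2 between 3.84 and 13.1, and Hbb-bt between 4.86 and 14.8.

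All tests of explanations in the paragraphs below were chosen after the results were seen. Microglial and other immune genes lay higher in the libraries labelled shCSB/shNDN. A lower share of neuronal RNA would raise every other cell type alike, and the 3 lists tested argue against it. The microglia median lay above those of astrocytes, myelin and endothelium by at least 0.476 (log2) in both libraries, against at most 0.086 in a control library. Meningeal and fibroblast markers, left out of that test, were at 0.73 in replicate 1 and 0.42 in replicate 2. In replicate 2 they came closer to the microglia median of 0.54, so the size of the gap depends on the lists chosen. More microglia in an unchanged state, as the only source of the rise, are argued against by a gap of at least 1.35 between activated and homeostatic microglia genes. The largest such gap in a control library was 0.034. Control libraries are measured against their own mean, which keeps both kinds of control gap small. In shCSB, the activated and homeostatic medians were 0.20 and 0.10 in replicate 1, and 0.21 and 0.52 in replicate 2. The microglia medians there were 0.18 and 0.43, with the highest of the 3 other medians tested at 0.039 and 0.24. Meningeal and fibroblast markers lay above the microglia markers in shCSB, at 0.82 and 0.54. The homeostatic genes themselves were at 1.66 in replicate 1 and 0.40 in replicate 2, so more microglia beside another change stay open. Which cells the RNA of the activated genes came from was not tested, so a change of microglial state is not shown. In replicate 2 the members went both ways. P2ry12 had an FPKM of 3.51 against 7.94 and 8.47 in shControl, and P2ry13 one of 0.647 against 3.30 and 2.36. Siglech lay between the controls, and Tmem119, Cx3cr1, Gpr34, Sall1 and Fcrls above them. The added Ndn hairpin stays open as a hypothesis, since the activated list was at 3.74 in replicate 1, where Ndn was low, and at 1.74 in replicate 2, where Ndn lay in the range of shCSB, and 1 library of each kind cannot decide, nor separate the hairpin from the dose of virus or the injury of the injection, which were not tested.

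Replicate 2 of shCSB/shNDN stood apart in 3 ways. Hormone transcripts were present, with 50 reads of Gh against at most 2 in another library, 50 of Prl against 3, 286 of Pomc against 52, 228 of Avp against 18, and 95 of Oxt against 9. Traces of pituitary tissue stay open, since of the 9 pituitary markers other than Gh, Prl and Pomc only 1, Pou1f1 with 8 reads against 1, exceeded the 95% upper limit of the highest other library, and 0 of 12 hypothalamus markers other than Avp and Oxt did. These limits cover counting error only, not the amplification of a few molecules. The low mitochondrially encoded RNA is not accounted for by the authors' scaling, since its median of -2.30 stayed at -1.91 or lower with other scalings. The ratio of genes at 1 read to genes at 10 reads was 1.82, against 6.52 or more elsewhere, which is consistent with amplification of few RNA molecules, and no biological explanation was tested.

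Ercc6 was not lower in the libraries labelled shCSB. Exchanged labels between shControl and shCSB with a halving of Ercc6 by the hairpin are argued against, since the 95% interval of the log2 change from shCSB to shCSB/shNDN had its lower end at -0.284. An exchange with a smaller loss stays open. A halving in the whole tissue hidden by the spread is argued against by an interval of the change from shControl to shCSB with its lower end at -0.434. A loss in a small share of the cells stays open, since this interval leaves room for a loss of up to 26.0%, and the data hold no measure of the share of cells that took up the virus. The libraries labelled shCSB/shNDN, whose label also names the CSB hairpin, leave less room. Their Ercc6 level on the scale of the recovered reads was 127% of that in shControl, with a 95% interval from 87.9% to 185%. A lower protein level without a lower transcript level was not tested.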
